A study of Mus musculus with 12 samples.

How the data were processed

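Poly(A)-selected RNA libraries from isolated splenic B cells and dendritic cells of 12-week-old NOD and NOD.Idd2 mice were used, 3 per group and 12 in all. RNA was extracted with Trizol and libraries were made with a KAPA HyperPrep kit, per the labels' protocols. The submitters' processing notes name STAR, with the version written as 0.12.2, and the genome build GRCm38. The counting tool, the annotation, the use of strand and any filters are not given in the sources used here. The authors deposited a table of raw counts, whole numbers per gene symbol, and a table of normalized counts, treated here as a signal. In the deposited normalized signal each library's values were its counts divided by a single size factor, and these factors lay within 0.01% of median-of-ratios factors computed within each cell type, so that table was not used across cell types. Samples were assigned to groups and replicate numbers from their titles.

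Of 28188 gene symbols, 27693 were matched to GENCODE and 397 to RefSeq gene positions on GRCm38, 6 were ambiguous and 92 were unmatched. CPM values were computed with TMM scaling in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. The main test was edgeR's quasi-likelihood test on the 6 libraries of each cell type, NOD.Idd2 against NOD, with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference of strain effects between cell types and the comparison of NOD dendritic cells with NOD B cells were contrasts in a fit of all 12 libraries in 4 groups. Calls on each chromosome against all others, and the overlap of calls between cell types, were tested with Fisher's exact test.

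Gene sets were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, over 41 lists fixed beforehand, of which those with at least 3 tested members entered. The lists cover markers of spleen cell types, immune response pathways and general cell functions. With an estimated in place of the preset correlation, no set passed in either cell type. For a gene with 0 counts in a group, the fold is a bound against a floor of 3 counts over the 3 libraries, and for 1 count a 95% counting interval is given. Intervals and floors cover counting error only.

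Genes were named by rule: among called genes with at least 5 CPM in the higher group, the 10 largest increases and 10 largest decreases and the 5 smallest p-values not yet named, up to 4 called members of each list, the 8 shared genes with the smallest larger p and the 8 smallest p-values of the interaction. Results for some genes that the rule would name are not reported here. Provisional symbols and antigen receptor segments were counted, not named. Genes outside the rule are list members given with their values, chromosome 9 genes and Capn11.

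The labels give both strains replicate numbers 1 to 3. In B cells the deviations of same-numbered libraries from their group means correlated at 0.617, 0.410 and 0.815, above 0.1 for every pair. However, NOD replicate 1 correlated at 0.433 with NOD.Idd2 replicate 2, and NOD replicate 2 at 0.470 with NOD.Idd2 replicate 1. The data thus match replicate 3 across the strains but do not tell replicates 1 and 2 apart, and the labels state no pairing. The block assumes that all 3 numbers pair the B cell libraries. For B cells a fit with the replicate number as a block is given beside the counts, sets and list members reported whose call it changes. Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no filter on low counts, a filter at 1 CPM in 3 libraries, a fit of all 12 libraries, limma on the deposited normalized counts plus 1, a 1.5-fold minimum, the block and each library left out. Leaving out both replicate 3 B cell libraries, a term for them, a set test of the interaction, and the block with an estimated correlation were added after seeing the data. So were the tests of windows, class I sums and plasmacytoid markers, and the assignments of strain labels for the difference between cell types, of which those that part all 3 B cell pairs were run in full.

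The tests were run once per fit on simulated counts in which the changed genes were known. All changed genes were drawn from those with a mean above 5 CPM, so the recovery rates do not cover lower genes. The counts simulated without the block held no shared shift of replicate 3. Those with the block took the pairing by number as given. In the B cell comparison of 15011 genes 59.7% of 1.5-fold, 94.0% of 2-fold and 100% of 4-fold changes were recovered, with 8.15% false calls, and 100% at every size with the block. In the dendritic cell comparison of 14441 genes 92.5% of 1.5-fold and 100% of larger changes were recovered, with 7.14% false calls. For the difference between cell types, over 16588 genes, recovery was 56.7%, 88.1% and 98.5%, with 4.14% false calls.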

Results

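RNA from B cells and from dendritic cells isolated from the spleens of 12-week-old mice was sequenced as poly(A)-selected libraries. NOD mice, which develop autoimmune diabetes spontaneously, were the control strain. NOD.Idd2 mice carry the Idd2 diabetes locus from B10 mice on the NOD background, and the series asks what this locus does to gene expression. There were 4 groups of 3 libraries: NOD B cells, NOD.Idd2 B cells, NOD dendritic cells and NOD.Idd2 dendritic cells. The 6 B cell libraries held 40344883 to 44632276 counts and 21042 to 21588 detected genes each. The dendritic cell libraries held 24627488, 26811142 and 26451494 counts in NOD and 22769062, 30337812 and 8663421 counts in NOD.Idd2, so that replicate 3 of NOD.Idd2 was the shallowest, with 18120 detected genes. No pair of libraries within a group agreed within sampling noise, the lowest chi-square per gene being 3.49. The labels do not say whether the libraries come from separate animals, so the p-values measure only the spread between these samples. The strain and cell type comparisons, the gene lists and the rule for named genes were fixed before the data were examined, and tests added later are named with the processing. Values below are CPM, counts scaled by library size, mean ± SD over n = 3 libraries, and log2 fold changes are NOD.Idd2 minus NOD, with their standard error (SE).

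The isolated populations carried the transcripts that define B cells and dendritic cells. Among the NOD libraries, the antigen receptor subunit gene Cd79a was at 1554 ± 106 CPM in B cells and 4.14 ± 2.83 in dendritic cells. In the other direction Itgax, which encodes the integrin CD11c, was at 2.90 ± 0.184 CPM in B cells and 2127 ± 148 in dendritic cells, and Flt3, the receptor for the dendritic cell growth factor Flt3 ligand, was at 2.21 ± 0.422 and 664 ± 38.6. Genes of both conventional dendritic cell types were higher in the dendritic cell libraries, with Xcr1 and Clec9a of type 1 at 141 ± 9.58 and 131 ± 17.2 CPM, and Clec4a4 and Cd209a of type 2 at 135 ± 9.59 and 329 ± 37.1 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 12675 of 16588 genes differed between NOD dendritic cells and NOD B cells, 6257 higher and 6418 lower in dendritic cells. All 18 genes of the B cell identity list were higher in B cells, and 11 of 12 on the type 1, 12 of 14 on the type 2 and 11 of 12 on the general dendritic cell list were higher in dendritic cells. The dendritic cell libraries also carried more of the macrophage marker Adgre1, at 278 ± 55.4 against 17.9 ± 2.60 CPM. The cell types differed in sex as well: Xist, transcribed from the inactive X chromosome of females, was at 1586 to 2126 CPM in the B cell libraries and at 1 to 4 counts in each dendritic cell library, whereas the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in every B cell library and 243 to 300, 82.8 to 110, 111 to 125 and 147 to 156 CPM in dendritic cells. Each strain comparison was therefore made within 1 sex, and every difference between cell types is also a difference between sexes.

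In B cells, 10 of the 24 genes that changed between the strains in the main fit lay on chromosome 9. Jhy (chromosome 9, 40894849 to 40964118), a gene required for normal brain ventricle development, was at 78.0 ± 5.07 CPM in NOD and nearly undetected in NOD.Idd2, with 9960 counts against 1 over the 3 libraries, a ratio of 9738 with a 95% counting interval of 1747 to 384652. Its neighbour Crtam (40969691 to 41004628), a lymphocyte surface protein that binds the adhesion molecule Cadm1, fell from 7.71 ± 1.06 to 0.564 ± 0.220 CPM (log2 -3.77, SE 0.27). Ubash3b, a phosphatase that restrains antigen receptor signalling, fell from 48.1 ± 6.39 to 20.2 ± 1.74 CPM (log2 -1.25, SE 0.11). Nxpe2 (chromosome 9, 48318006 to 48353454) rose from 13.5 ± 1.48 to 81.4 ± 4.49 CPM (log2 2.59, SE 0.09), and Slc37a2, a sugar phosphate transporter at 37227585 to 37255738, rose from 30.6 ± 3.85 to 95.9 ± 5.93 CPM (log2 1.65, SE 0.10).

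Genes on other chromosomes changed as well. Suclg2 on chromosome 6, a subunit of the mitochondrial succinyl-CoA ligase, rose from 6.25 ± 1.05 to 31.7 ± 3.63 CPM (log2 2.34, SE 0.14). Tnfrsf21 on chromosome 17, which encodes death receptor 6, rose from 4.29 ± 0.469 to 19.3 ± 0.912 CPM (log2 2.17, SE 0.10). Desi1 on chromosome 15, a SUMO isopeptidase, rose from 15.2 ± 0.341 to 42.1 ± 2.60 CPM (log2 1.47, SE 0.06), and Slfn5 on chromosome 11 rose from 79.6 ± 2.52 to 106 ± 3.46 CPM (log2 0.42, SE 0.04). H2-D1 in the major histocompatibility complex of chromosome 17, which encodes a classical class I heavy chain, fell from 1000 ± 59.4 to 352 ± 46.4 CPM (log2 -1.51, SE 0.10). The pseudogene Nxpe1-ps rose from 3.12 ± 0.333 to 9.77 ± 0.523 CPM (log2 1.65, SE 0.11). Reads from Nxpe2, Nxpe4 and Nxpe1-ps, and from the class I genes, can be shared between near-identical copies, and the annotated span of Nxpe4 (48162023 to 48400025) covers Nxpe2 on the opposite strand, so these values are uncertain as levels of single genes.

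Of 15011 genes tested in B cells, 24 passed an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 11 higher and 13 lower in NOD.Idd2, against 961 at an unadjusted p under 0.05. Adjusted p ranged from 1.98e-06 for Jhy to 0.0250 for Slfn5 among the 11 genes named, and 9 of the 24 had only provisional symbols. Replicate 3 of both strains stood apart from replicates 1 and 2, and with the replicate number as a block the count was 156 (75 higher, 81 lower), among them all 24. With a term for replicate 3 alone, the only match across strains that the data show, it was 74 (40 higher, 34 lower). Without both replicate 3 libraries it was 46. It fell to 15 without NOD replicate 2, 13 without NOD.Idd2 replicate 1 and 14 without NOD.Idd2 replicate 2. Slfn5 was lost on leaving out any of the 6 libraries (adjusted p 0.0609 to 0.185) and in a fit of all 12 libraries (0.537), and Ubash3b without NOD.Idd2 replicate 1 (0.0701) or replicate 2 (0.0810).

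**Figure D1:**
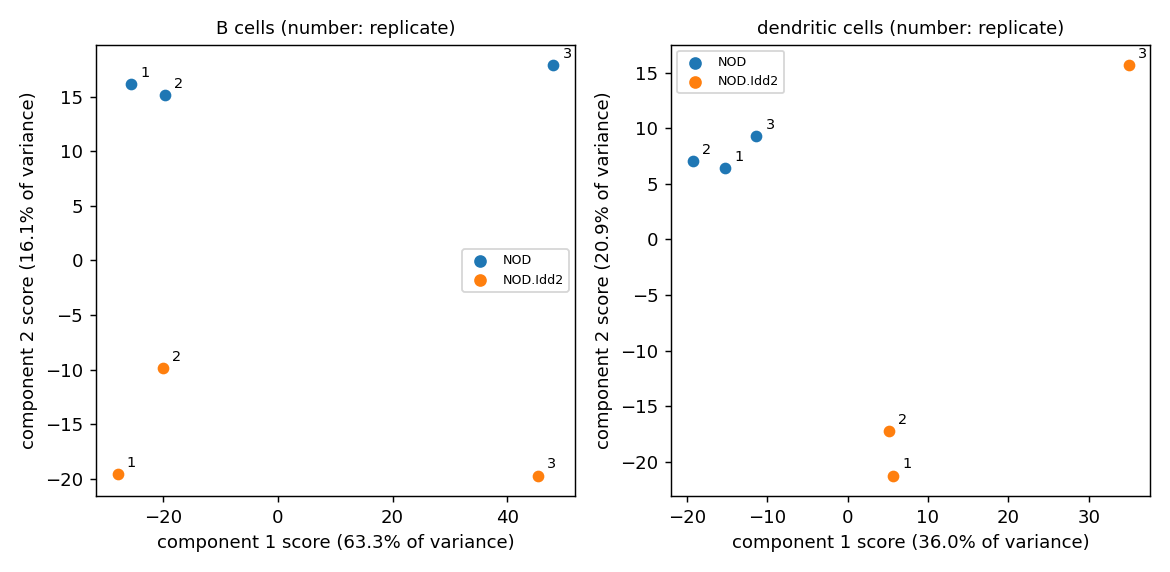
Scores of the 6 libraries of each cell type on principal components 1 and 2 of log2 CPM, with strain by colour and replicate by number. In B cells component 1 (63.3% of variance) separates replicate 3 of both strains from replicates 1 and 2, and component 2 (16.1%) separates the strains. In dendritic cells NOD.Idd2 replicate 3 lies apart on component 1 (36.0%).

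In NOD.Idd2 B cells several lists passed the set test with the preset correlation but not with an estimated one, and without the replicate block none of their members passed over all genes. The type I interferon response list had 24 of 30 members above 0, with a median log2 change of 0.23, and passed the set test (camera, adjusted p = 8.27e-06). Its summed level was 1260 ± 86.9 CPM in NOD and 1293 ± 68.7 in NOD.Idd2, a change within the SD. No member passed over all genes and 1, Ifi27l2a (log2 0.67, SE 0.08), passed when adjusted over the list alone. The antiviral genes Ifit1 (log2 0.74, SE 0.19) and Ifit3 (0.67, SE 0.27) did not pass, with adjusted p = 0.606 and 0.774, but with the replicate block they did, at 0.0355 and 0.0381, as did Ifi27l2a (7.14e-05). The cholesterol synthesis list had 19 of 20 members above 0 (median 0.14, adjusted p = 3.77e-07), with 0 passing over all genes and 6 when adjusted over the list alone, among them the sterol regulator Srebf2 (log2 0.28, SE 0.06) and Sc5d (0.37, SE 0.06). With the block 4 of the 20 passed over all genes, all higher, among them Srebf2 (adjusted p = 0.00309) and Sc5d (0.00474). With the block the constitutive chaperone gene Hspa8 passed over all genes (log2 1.29, SE 0.08, adjusted p = 7.60e-06, against 0.726 without the block). The cell cycle list had 27 of 28 members above 0 (median 0.21, adjusted p = 1.80e-05) with 0 passing either way, Mki67 being at 43.5 CPM in NOD and 54.2 in NOD.Idd2. With the block 1 of the 28, Nusap1 (log2 0.86, SE 0.14, adjusted p = 0.0184), passed over all genes. Oxidative phosphorylation genes were above 0 for 25 of 28 (median 0.05, adjusted p = 0.0239). With an estimated correlation none of these 4 lists passed, at adjusted p = 0.632 each.

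Natural killer cell and neutrophil markers, and most monocyte markers, had fitted changes below 0 in the NOD.Idd2 B cell libraries, but not the markers of every other cell type. All 12 natural killer cell genes lay below 0 (median log2 -0.45, adjusted p = 5.92e-05 by camera), as did all 9 neutrophil genes (median -1.14, adjusted p = 6.14e-05) and 7 of 8 monocyte genes (median -0.37, adjusted p = 0.00742). Their levels were low: the neutrophil list summed to 22.4 ± 12.0 CPM in NOD and 10.8 ± 2.39 in NOD.Idd2, and the natural killer list to 39.3 ± 6.85 and 28.8 ± 7.66. The monocyte list summed to 174 ± 2.78 and 180 ± 10.9 CPM, so its summed level did not fall although 7 of 8 fitted changes lay below 0. T cell genes lay above 0 for 17 of 19 (median 0.20) and summed to 175 ± 12.4 and 195 ± 63.1 CPM. That set did not pass (adjusted p = 0.591), and it passed as lower without NOD.Idd2 replicate 1 (0.0161) and as higher without NOD.Idd2 replicate 2 (1.48e-06). The unfolded protein response list (median -0.07, adjusted p = 0.000827), the plasma cell list (median -0.10, 0.0239) and the dendritic cell maturation list (median -0.08, 0.0495) were also lower as sets. For all 6 of these lists adjusted p = 0.632 with an estimated correlation, none of their members passed over all genes, and 1 monocyte gene (Chil3) and 1 neutrophil gene (Mmp8) passed when adjusted over the list alone. With the replicate block members did pass over all genes: Gzma (log2 -0.85, adjusted p = 0.00605) of the natural killer list, Chil3 (-1.84, 0.0202) of the monocyte list, Hsp90b1 (-0.22, 0.0145) of the unfolded protein response list, and 3 of 21 on the plasma cell list, 1 higher and 2 lower. The maturation list did not pass with the replicate block (adjusted p = 0.126) or without NOD replicate 1 (0.0672), NOD replicate 2 (0.0911) or NOD.Idd2 replicate 1 (0.0818), 2 (0.156) or 3 (0.0716).

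The plasma cell set was lost without NOD replicate 1 (adjusted p = 0.0993) or 3 (0.0864), or NOD.Idd2 replicate 2 (0.296) or 3 (0.119), and the monocyte set without NOD replicate 1 (0.0672) or NOD.Idd2 replicate 2 (0.0927). Oxidative phosphorylation was lost without NOD replicate 2 (0.0911) or 3 (0.362), or NOD.Idd2 replicate 1 (0.206) or 3 (0.0501). Without both replicate 3 libraries the plasma cell (0.281), oxidative phosphorylation (0.187) and unfolded protein response (0.0521) sets were lost. The other 29 of 39 set tests in B cells did not pass (adjusted p 0.105 to 0.999), among them B cell identity, marginal zone, follicular and transitional B cell markers, class II presentation and B cell receptor signalling. On the class I presentation list H2-D1 passed over all genes and when adjusted over the list alone, and the set did not (adjusted p = 0.479). With the replicate block H2-K1 passed as well (log2 0.44, SE 0.03, adjusted p = 4.51e-05), and so did 1 of 18 B cell identity genes.

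In dendritic cells the strains differed in 186 genes in the main fit, against 24 in B cells. With the replicate block the counts were 214 and 156, and the difference between cell types in these counts was not tested. Nxpe4 on chromosome 9 rose from 2.87 ± 0.424 to 82.8 ± 1.48 CPM (log2 4.85, SE 0.09), and Zbtb16 (48654297 to 48836222), the transcription factor PLZF, rose from 0.599 ± 0.293 to 5.73 ± 1.06 CPM (log2 3.22, SE 0.29). The cystine transporter gene Slc7a11 on chromosome 3 rose from 3.97 ± 0.548 to 24.8 ± 0.899 CPM (log2 2.64, SE 0.11). The constitutive chaperone gene Hspa8 on chromosome 9 rose from 176 ± 60.8 to 487 ± 44.2 CPM (log2 1.47, SE 0.19), and Pigr, the polymeric immunoglobulin receptor, from 1.90 ± 0.416 to 5.46 ± 0.677 CPM (2.82-fold, SE of log2 0.20). Desi1 (log2 2.23, SE 0.11), Suclg2 (2.05, SE 0.10), Nxpe1-ps (1.67, SE 0.07) and Slc37a2 (1.38, SE 0.12) rose as in B cells. Jhy had 134 counts over the NOD libraries and 0 over the NOD.Idd2 libraries, at least 35.4-fold lower against a floor of 3 counts over the group. Capn11 on chromosome 17, a calpain protease gene chosen after its values were seen, had 0 and 138 counts, at least 58.0-fold higher in NOD.Idd2.

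Several class I genes fell. H2-Q6 fell from 218 CPM (190, 238 and 225 in the 3 libraries) to 28.3 ± 1.37 CPM (log2 -2.94, SE 0.09) and H2-D1 from 1625 ± 66.9 to 511 ± 16.9 CPM (log2 -1.67, SE 0.05). H2-Q7 fell from 122 ± 13.3 to 13.3 ± 19.1 CPM (log2 -3.80, SE 0.66), with 2.28, 2.30 and 35.3 CPM in the 3 NOD.Idd2 libraries, and it did not pass without NOD.Idd2 replicate 1 (adjusted p = 0.0997) or 2 (0.0978). DESeq2 gave it 0.198. H2-K1, the other classical class I gene, rose from 650 ± 60.8 to 1004 ± 77.6 CPM (log2 0.63, SE 0.07). Further decreases were in Nbea on chromosome 3 (log2 -1.45, SE 0.10), the ubiquitin ligase gene Mid1 (-1.26, SE 0.13), the endocytic adaptor gene Hip1 (-1.10, SE 0.10), Gp2 (-1.01, SE 0.13), D7Ertd128e (-0.91, SE 0.16), Hic1 (-0.86, SE 0.12), Lekr1 (-0.81, SE 0.16) and the histamine receptor gene Hrh1 (-0.73, SE 0.06). Col17a1 (log2 0.91, SE 0.07), Rpl7l1 (0.72, SE 0.06) and the inhibitory IgG receptor gene Fcgr2b (0.67, SE 0.07) rose.

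Of 14441 genes tested in dendritic cells, 186 passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 96 higher and 90 lower in NOD.Idd2, against 1638 at an unadjusted p under 0.05. Of the 186, 84 changed by at least 1.5-fold, 24 had only provisional symbols and 2 were immunoglobulin segments. The count was 332 without NOD replicate 3, with 138 higher and 194 lower, so the balance of directions depended on the fit. It fell to 118 without NOD replicate 2 and to 71, 63 and 77 without NOD.Idd2 replicates 1, 2 and 3, replicate 3 being the shallow library. DESeq2 called 286 genes, the fit without a filter on low counts 700 and the fit of all 12 libraries 94. In that fit 16 of 49 named genes were lost, among them Hspa8 (adjusted p = 0.0974) and Mmp9 (0.113). Of the 49, 30 passed whichever library was left out. D7Ertd128e was lost without NOD.Idd2 replicate 1, 2 or 3 (adjusted p 0.107, 0.136 and 0.0684), Hic1 without replicate 1 (0.0545), and Lekr1 without NOD replicate 2 (0.111) or NOD.Idd2 replicate 1, 2 or 3 (0.164, 0.0854 and 0.123).

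**Figure D2:**
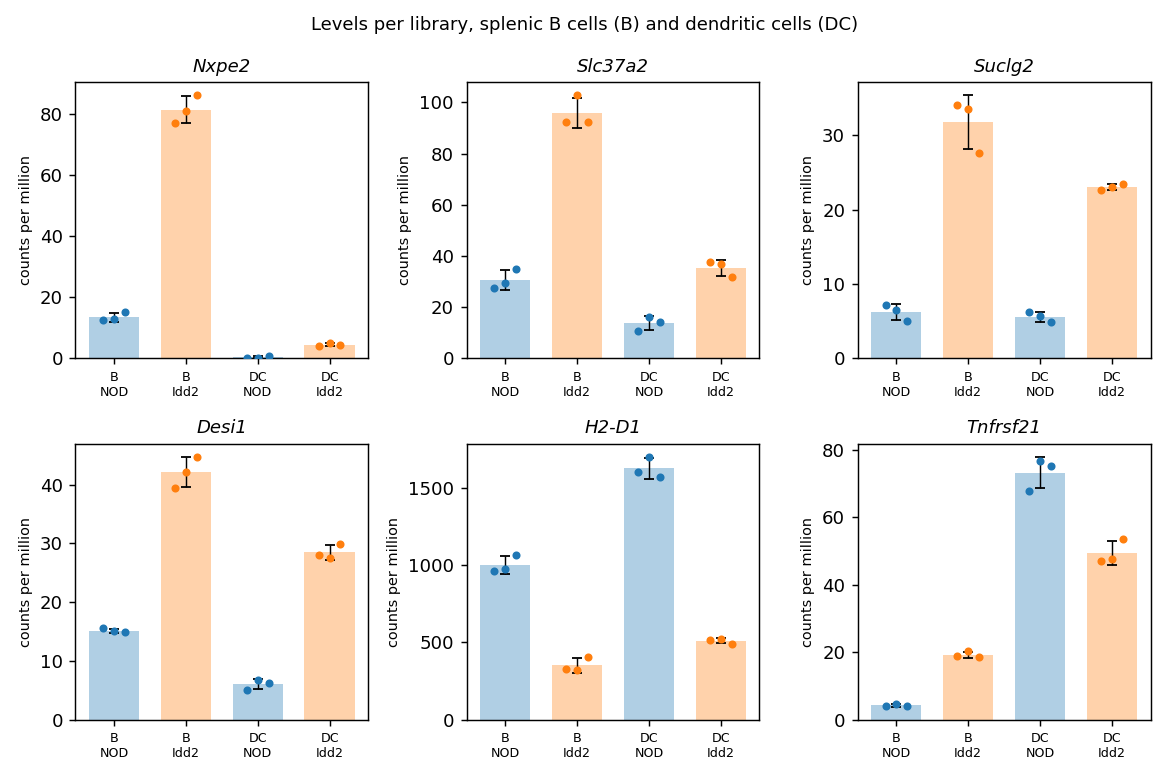
CPM of 6 genes in each library (points), with the mean of 3 libraries (bars, from 0) and the SD (error bars), for NOD (blue) and NOD.Idd2 (orange) in B cells and dendritic cells. Nxpe2, Slc37a2, Suclg2 and Desi1 are higher in every NOD.Idd2 library of either cell type, H2-D1 is lower, and Tnfrsf21 is higher in B cells (4.29 to 19.3 CPM) and lower in dendritic cells.

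Interferon response genes were lower in NOD.Idd2 dendritic cells. On the type I interferon list 2 of 31 members lay above 0 (median log2 -0.24, adjusted p = 1.44e-10 by camera), 6 passed over all genes and 20 when adjusted over the list alone, 19 of them lower. Among the called genes were the antiviral oligoadenylate synthetase genes Oas2, from 65.5 ± 1.57 to 41.9 ± 7.33 CPM (log2 -0.62, SE 0.10), Oas1a (-0.49, SE 0.08) and Oasl2 (-0.65, SE 0.13), the nucleic acid sensor gene Zbp1 (-0.51, SE 0.09) and, in the other direction, Ifi27l2a (0.52, SE 0.11). The interferon gamma list was lower as a set (median -0.13, adjusted p = 0.000122), with 1 of 21 members passing over all genes and 1 when adjusted over the list alone. The class I presentation list was lower too (median -0.11, adjusted p = 0.00125), with H2-D1, H2-Q7 and the class I transactivator gene Nlrc5 (-0.29, SE 0.05) lower and H2-K1 higher over all genes, and 11 of 21 members, 9 of them lower, when adjusted over the list alone. With an estimated correlation adjusted p = 0.667 for each of the 3 lists. In the fit of all 12 libraries Oas2 (0.138), Oas1a (0.209), Nlrc5 (0.249) and H2-Q7 (0.246) did not pass. Oas1a was also lost without NOD.Idd2 replicate 1 (0.0800) or 3 (0.0609). Without NOD replicate 2 or NOD.Idd2 replicates 1, 2 or 3, adjusted p was 0.0592, 0.116, 0.0997 and 0.122 for Zbp1 and 0.0674, 0.0549, 0.149 and 0.115 for Nlrc5.

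Cell cycle genes were higher in NOD.Idd2 dendritic cells. All 28 members lay above 0 (median log2 0.33, adjusted p = 2.15e-13 by camera), 5 passed over all genes and 15 when adjusted over the list alone, all higher. Mki67, a marker of cycling cells, rose from 179 ± 10.5 to 253 ± 20.2 CPM (log2 0.50, SE 0.07), and the mitotic genes Top2a (0.58, SE 0.08), Nusap1 (0.82, SE 0.14) and Kif11 (0.62, SE 0.11) rose too. Cholesterol synthesis genes were above 0 for 16 of 20 (median 0.19, adjusted p = 0.00125), with 0 passing over all genes and 8 when adjusted over the list alone, such as Sqle (0.41, SE 0.10) and Sc5d (0.29, SE 0.06). With an estimated correlation adjusted p = 0.667 for both lists. In the fit of all 12 libraries Mki67 (0.117), Top2a (0.0714), Nusap1 (0.0974) and Kif11 (0.129) did not pass. Nusap1 was also lost without NOD.Idd2 replicate 2 (0.132) or 3 (0.108), Kif11 likewise (0.189 and 0.128), and the cholesterol set without NOD replicate 3 (0.1001).

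Some marker lists of dendritic cell types and of other cells passed the set test with the preset correlation, with few or no members passing singly. The type 2 conventional dendritic cell list was higher in NOD.Idd2 (median log2 0.13, adjusted p = 0.0112 by camera). Its lectin gene Mgl2 rose from 29.7 ± 0.902 to 45.8 ± 3.59 CPM (log2 0.63, SE 0.07), and 7 of 14 members passed when adjusted over the list alone, 6 higher and Esam lower. On the type 1 list Cadm1, a chromosome 9 gene, fell from 86.6 ± 10.8 to 53.4 ± 3.28 CPM (log2 -0.69, SE 0.09) and 2 of 12 members, both lower, passed when adjusted over the list alone, and the set did not pass (adjusted p = 0.694). Natural killer genes were above 0 for 10 of 11 (median 0.35, adjusted p = 0.00976), T cell genes for 16 of 19 (median 0.22, 0.0300), transitional B cell genes for 7 of 7 (median 0.30, 0.00403) and unfolded protein response genes for 17 of 22 (median 0.09, 0.0246). None of these members passed over all genes, and 2 transitional B cell genes, Cd24a and Myb, passed when adjusted over the list alone. With an estimated correlation adjusted p = 0.667 for the type 2, natural killer and transitional lists and 0.685 for the T cell and unfolded protein response lists. The natural killer list summed to 344 ± 30.8 CPM in NOD and 350 ± 9.47 in NOD.Idd2, the T cell list to 540 ± 23.8 and 544 ± 6.79, the monocyte list, which did not pass as a set, to 832 ± 130 and 1032 ± 14.7, and the B cell identity list to 1285 ± 88.5 and 1544 ± 321.

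The type 2 dendritic cell set was lost without NOD replicate 3 (adjusted p = 0.193), the transitional set without NOD replicate 2 (0.0596) and the natural killer set without NOD.Idd2 replicate 2 (0.0535). The T cell set was lost without NOD replicate 2 (0.722) or NOD.Idd2 replicate 2 (0.0612) or 3 (0.147), and the unfolded protein response set without NOD replicate 1 (0.431) or NOD.Idd2 replicate 2 (0.120) or 3 (0.0623). The other 30 of 40 set tests in dendritic cells did not pass (adjusted p 0.0797 to 0.863), among them plasmacytoid and general dendritic cell markers, dendritic cell maturation, class II presentation, macrophages, monocytes and neutrophils.

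Single members of lists that did not pass as sets also changed in dendritic cells. The macrophage scavenger receptor gene Cd163 rose (log2 0.77, SE 0.15) and the protease gene Mmp9 on the neutrophil list fell (-0.53, SE 0.07). Of genes that act in antigen receptor signalling, Cd72 (-0.44, SE 0.05) fell while Fcgr2b rose. The cytokine gene Tnf fell from 20.7 ± 2.37 to 13.5 ± 1.53 CPM (log2 -0.61, SE 0.11) and its neighbour Ltb rose from 198 ± 22.4 to 262 ± 11.8 CPM (0.40, SE 0.07). Ahnak (0.65, SE 0.12) rose, and the adhesion gene Jaml (-0.36, SE 0.07), the apoptosis gene Pmaip1 (-0.45, SE 0.06), Asb2 (-0.33, SE 0.06), Dtx1 (-0.26, SE 0.05) and the inhibitory ligand gene Pdcd1lg2 (-0.30, SE 0.06) fell. These passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. On leaving out single libraries, calls were lost for Cd163 without NOD.Idd2 replicate 1 (0.125), 2 (0.205) or 3 (0.0681), for Ahnak (0.0910, 0.114 and 0.144) and Asb2 (0.0984, 0.114 and 0.140) without the same 3, and for Tnf without NOD replicate 2 (0.0790) or NOD.Idd2 replicate 2 (0.163) or 3 (0.115). Without NOD replicate 2 or NOD.Idd2 replicate 1, 2 or 3, adjusted p was 0.0750, 0.116, 0.0758 and 0.123 for Ltb, 0.0578, 0.0723, 0.189 and 0.0881 for Dtx1, 0.141, 0.181, 0.153 and 0.208 for Jaml and 0.190, 0.224, 0.244 and 0.144 for Pdcd1lg2. Without NOD replicate 3 it was 0.0597 for Jaml and 0.0611 for Pdcd1lg2, which was also lost with a replicate block (0.0560). In the fit of all 12 libraries Cd163 (0.119), Ahnak (0.143), Asb2 (0.148), Jaml (0.117), Mmp9 (0.113) and Pdcd1lg2 (0.0595) were lost.

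**Figure D3:**
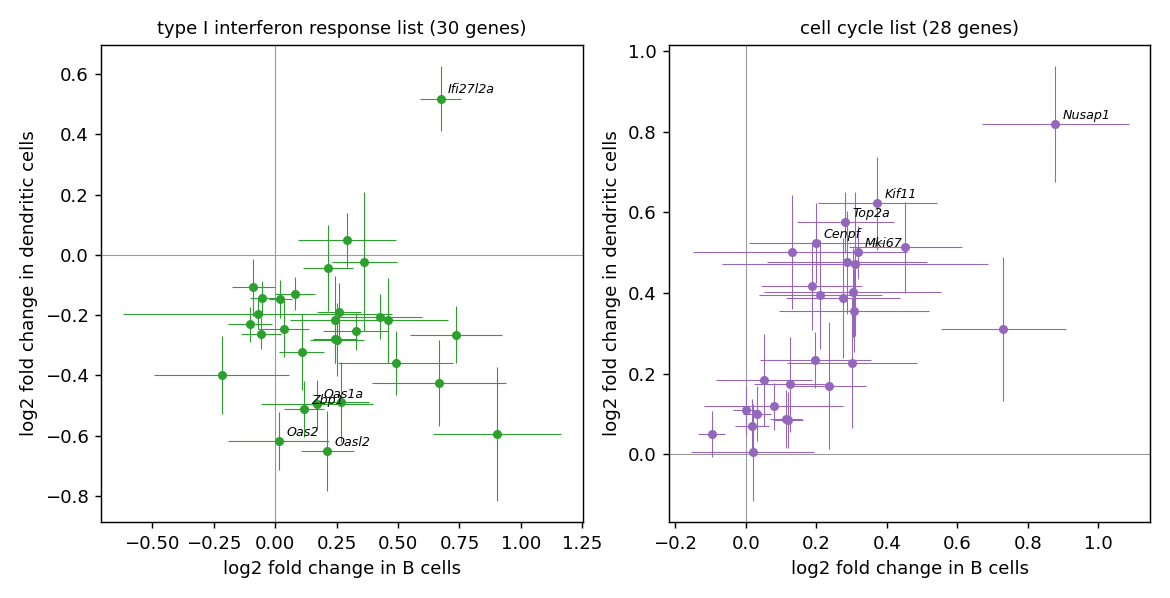
Log2 fold changes (NOD.Idd2 minus NOD) of each member of the type I interferon response list (30 genes) and the cell cycle list (28 genes), B cells on the horizontal and dendritic cells on the vertical axis, with SE bars. Of genes that passed over all genes in dendritic cells, those with larger changes are named. Most interferon genes lie to the right of 0 and below it, and the cell cycle genes lie above 0 on the vertical axis.

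Because Idd2 maps to chromosome 9, the changed genes were counted by chromosome. In B cells 10 of 868 tested chromosome 9 genes changed (1.15%) against 14 of 14098 elsewhere (0.0993%), an odds ratio of 11.7 (Fisher's exact test, two-sided, p = 3.81e-07, adjusted over chromosomes 7.61e-06). All 10 started between 37.2 and 48.4 Mb, 5 higher and 5 lower. In dendritic cells 20 of 820 chromosome 9 genes changed (2.44%) against 1.22% elsewhere (odds ratio 2.02, Fisher's exact test, p = 0.00596), which did not pass once adjusted over chromosomes (0.0596). Of these 20, 17 started between 37.2 and 48.7 Mb, and 12 were higher and 8 lower. Nxpe2, Nxpe4 and Nxpe1-ps, which can share reads, were called in both cell types and counted as separate genes in both tests. Chromosome 17 held 21 changed genes of 738 tested in dendritic cells (2.85%, adjusted p = 0.0123). As a set, all tested chromosome 9 genes did not pass camera in either cell type. Camera looks for a shift in a common direction, and the called genes went both ways, so it is no check on the Fisher tests. On the list of immune genes on chromosome 9, which as a set passed in neither cell type (adjusted p = 0.329 and 0.235), 0 of 38 members changed in B cells and 4 of 38 in dendritic cells, among them Zbtb16, Cadm1 and Jaml. When adjusted over the list alone these were 2 and 5. That list does not hold Crtam or Ubash3b, chromosome 9 genes that changed in B cells. With the replicate block 2 of 38 changed in B cells, both lower, among them Cadm1 (log2 -1.40, SE 0.28, adjusted p = 0.0464).

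**Figure D4:**
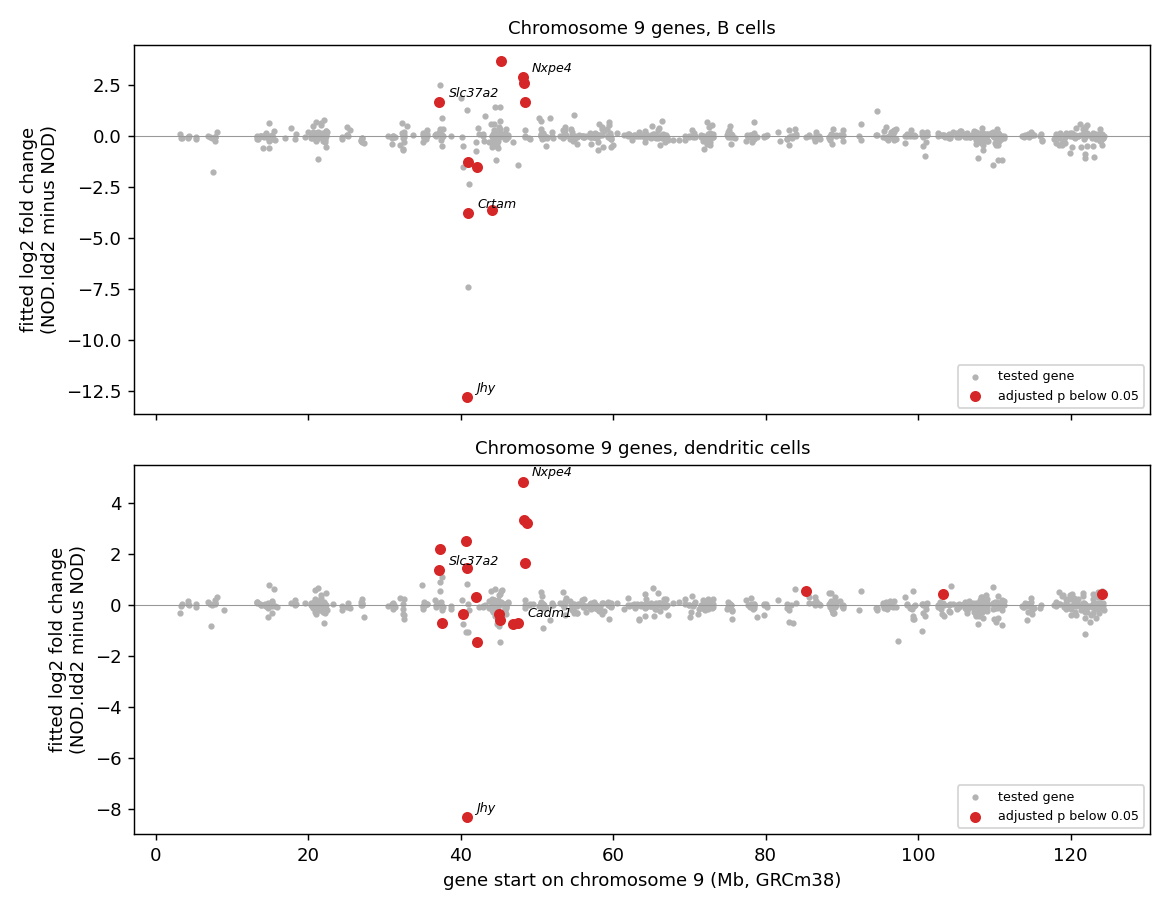
Fitted log2 fold change (NOD.Idd2 minus NOD) of each tested chromosome 9 gene by its start position in Mb (GRCm38), B cells above and dendritic cells below, with genes at adjusted p under 0.05 in red. The 10 called genes of B cells and 17 of 20 in dendritic cells lie between 37.2 and 48.7 Mb. The fitted value of Jhy, with 1 or 0 counts in NOD.Idd2, is no measure of its size.

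The changed genes overlapped between the cell types. Of 13028 genes tested in both, 20 were called in B cells and 152 in dendritic cells, and 16 in both (Fisher's exact test, p = 2.45e-28), 15 in the same direction. For genes that rose the overlap was 7, against 0.0518 for independent lists, and for genes that fell it was 8, against 0.0650. Desi1, Nxpe2, Slc37a2, Suclg2 and Nxpe1-ps rose and Jhy and H2-D1 fell in both. Tnfrsf21 was the exception, with log2 changes of 2.17 (SE 0.10) in B cells and -0.58 (SE 0.07) in dendritic cells. Across the 156 genes called in either cell type, which are not independent replicates, the fold changes correlated with Pearson's r of 0.765 and Spearman's rho of 0.509, and 97 had the same sign. Over all 13028 genes r was 0.404 and rho was -0.00133. With the replicate block in each cell type, 35 genes were called in both. With each of the 12 libraries left out in turn the overlap lay between 10, without NOD.Idd2 B cell replicate 1, and 16.

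For 18 genes the strain effect differed between cell types (10 higher and 8 lower in dendritic cells than in B cells, of 16588 tested, by edgeR's interaction test with Benjamini-Hochberg adjustment, against 1363 at an unadjusted p under 0.05). Tnfrsf21 differed most clearly (log2 difference -2.76, SE 0.11, adjusted p = 1.58e-07), rising from 4.23 ± 0.444 to 19.1 ± 0.976 CPM in B cells while it was at 74.5 ± 4.80 and 49.7 ± 2.83 in dendritic cells. The deubiquitinase gene Usp2 (3.72, SE 0.39) and Ubash3b (1.30, SE 0.15), both on chromosome 9, differed because they were lower in NOD.Idd2 B cells and little changed in dendritic cells, with Usp2 at 2.90 and 0.228 CPM in B cells and 0.354 and 0.369 in dendritic cells, and Ubash3b at 32.5 ± 2.15 and 33.6 ± 2.62 CPM in dendritic cells. Hip1 (-1.09, SE 0.13) and Cd72 (-0.53, SE 0.06) were lower in NOD.Idd2 dendritic cells relative to B cells, and Fcgr2b (0.67, SE 0.10) and the sorting receptor gene Sorl1 (0.60, SE 0.08) higher. As a set, the type I interferon genes differed between cell types (camera adjusted p = 1.39e-13), but not with an estimated correlation (adjusted p = 0.491 with an estimated correlation).

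With the replicate block 56 genes differed between cell types, 20 higher and 36 lower, 17 of them among the 18. That block also covered the dendritic cell libraries, which were not paired by number. Without NOD B cell replicate 2 there were 15, 4 higher and 11 lower, so the balance of directions depended on the fit. The count was 9 without NOD B cell replicate 1, 11 without NOD.Idd2 B cell replicate 1 or 2, and 9, 7 and 10 without NOD.Idd2 dendritic cell replicates 1, 2 and 3. Fcgr2b was lost without 5 of the 12 libraries, namely NOD B cell replicate 1 (adjusted p = 0.0592) or 2 (0.0640), NOD.Idd2 B cell replicate 1 (0.0648) or NOD.Idd2 dendritic cell replicate 1 (0.105) or 2 (0.0687). Sorl1 was lost without NOD.Idd2 dendritic cell replicate 2 (0.0703).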

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

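The splits of the libraries within each cell type and the sign test on chromosome 9 were planned; the tests of windows, class I sums and interferon genes, the set tests of the interaction, and the splits for the interaction and for the cell types were chosen only after the results were seen.

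In 18 genes the strain effect differed between cell types by the interaction test. The log2 difference, dendritic cell effect minus B cell effect, was -2.76 for Tnfrsf21, 3.72 for Usp2, 1.30 for Ubash3b, -1.09 for Hip1, -0.53 for Cd72, 0.60 for Sorl1 and 0.67 for Fcgr2b. Of 100 assignments of strain labels drawn within cell types, 2 gave as many genes, the real one and another with 75. That other draw turned all dendritic cell labels round, so that its contrast adds the strain effects that the real contrast subtracts. Those draws did not keep the B cell pairs. Among all 80 assignments that part the 3 B cell pairs as the real one does, the same 2 gave at least 18 genes (2.5%) and the highest of the rest gave 7. The rest mix the strains within at least 1 cell type, so that real strain effects add to the spread within groups. They therefore do not show how many genes would pass if the strain effects were equal in both cell types, and cannot exclude chance for the 18 genes. With the replicate block, applied to both cell types although the dendritic cell libraries were not paired by number, the real assignment gave 56. The turned one gave 149 and the highest of the rest 8.

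Sets that differed between cell types, by camera's adjusted p, were the type I interferon response (1.39e-13), natural killer (6.54e-06), monocyte, neutrophil and unfolded protein response (each 0.000341), plasma cell (0.00670), interferon gamma (0.0181), B cell receptor signalling (0.0424) and immune chromosome 9 lists (0.0424). With an estimated correlation all were lost, at adjusted p 0.491 to 0.653. Without the replicate 3 B cell libraries the plasma cell (0.0571) and immune chromosome 9 (0.106) sets were lost, and with the replicate block the latter (0.146). Sets were also gained, namely cell cycle and class I presentation with the block (each 0.0472, against 0.0797 and 0.0605) and immediate early genes without the replicate 3 B cell libraries (0.0342, against 0.293).

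For the strain comparisons, 6 libraries make only 10 splits, too few for a share under 0.05. In B cells 1 of 10 splits, the real one, gave 24 genes and the highest other gave 0, and with the replicate block the real split gave 156 while the splits that part as many pairs gave 0. In dendritic cells 1 of 10 gave 186 and the highest other 1. For NOD dendritic cells against NOD B cells, 1 of 10 gave 12675 and the highest other 0. Every other split mixes the strains, or in the last case the cell types, within both groups, so real effects widen the spread. The low counts of those splits therefore do not show how many genes would pass without an effect.

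The changed genes gathered in a segment of chromosome 9. If reads of NOD alleles aligned less well to the C57BL/6 reference than reads of B10 alleles, nearly all called genes there would be higher in NOD.Idd2, but 50% were lower in B cells (95% interval 18.7% to 81.3%) and 40% in dendritic cells (19.1% to 63.9%), which argues against this as the whole cause. A candidate explanation is regulatory variation in the segment that carries the B10 Idd2 locus, which was not tested separately. The design names the locus, and its bounds were not compared with the positions of the called genes. The gathering was also seen in B cells with the replicate block (Fisher's exact test, p = 1.02e-06). Alignment of reads from single genes such as Jhy stays open.

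Outside chromosome 9 the changed genes of dendritic cells also clustered. There 17 lay on chromosome 17 between 34.0 and 46.8 Mb, more than in any of 10000 random draws. This argues against scatter (permutation test, p = 0.0001, the smallest the draws can give). In B cells 4 lay on chromosome 3 between 52.7 and 67.5 Mb (permutation test, p = 0.0024). Among these 4, a provisional gene lies within the annotated span of another. The draws counted both as separate genes, so this test does not decide whether the genes called in the main B cell fit were scattered. With the replicate block the fullest B cell window was on chromosome 17, with 20 genes between 34.0 and 46.9 Mb (permutation test, p = 0.0001). Reads redistributed between the H2- genes do not account for the whole dendritic cell cluster. Without any H2- gene 12 genes remained (permutation test, p = 0.001), among them a provisional gene between H2-D1 and H2-Q6. In B cells the fullest chromosome 17 window without H2- genes held 2 genes in the main fit (permutation test, p = 0.0693). It held 18 with the replicate block (permutation test, p = 0.0001). The summed class I counts of 20 genes changed by a log2 of -0.55 in dendritic cells, from 3615 ± 148 to 2477 ± 76.0 CPM. This argues against redistribution among these 20 alone. Reads moved to genes outside the sum, or dropped by the unknown counting tool, stay open. Class I alleles that align less well in NOD.Idd2 stay open, because counts do not show mismatches. H2-K1 went the other way (log2 0.63), which does not decide it for the other class I genes. The clustered genes may mark further segments that differ between the strains, a hypothesis that the counts cannot settle.

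Most fitted changes of the type I interferon list lay below 0 in NOD.Idd2 dendritic cells and above 0 in NOD.Idd2 B cells. The list summed to 1934 ± 47.7 CPM in NOD and 1677 ± 91.5 in NOD.Idd2 dendritic cells. In B cells it summed to 1260 ± 86.9 and 1293 ± 68.7 CPM, a change within the SD. A lower share of plasmacytoid cells stays open. Their 12 markers had a median log2 change of 0.0898 (SD 0.24) against -0.24 for the interferon list. However, that marker list summed to 1626 ± 32.4 CPM in NOD B cells and 746 ± 73.2 in NOD dendritic cells. Of 13 members 7 were higher in dendritic cells and 4 in B cells, so the list does not track plasmacytoid cells alone. A single odd library is argued against, as the highest adjusted p of the set test over the 12 fits that leave out 1 library was 0.0239. Sex cannot be told apart from cell type, since 0 cell types hold both sexes. An opposite effect of strain on interferon signalling in the 2 cell types may be present, but with an estimated correlation neither set passed (adjusted p = 0.667 in dendritic cells and 0.632 in B cells), nor did the difference between them (0.491).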

How the results depend on the processing

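The set tests of the interaction, the fits that treat replicate 3 of the B cells apart and the block with an estimated correlation were chosen only after the results were seen. No result that passed changed direction under an alternative, but some sets that did not pass did, such as T cell genes in B cells and follicular genes in the interaction. Of the alternatives to summary results 83 stayed on their side of the threshold or within 1.5 times the count, 11 gained and 21 lost, and for single genes and sets 884 stayed and 183 were lost. The cause of each change below was not tested unless given. In B cells the 24 genes became 77 by DESeq2, 42 in a fit of all 12 libraries, 156 with the replicate block, 46 without both replicate 3 libraries, 74 with a term for replicate 3 and 13 to 18 with 1 library left out. In dendritic cells the 186 genes became 286 by DESeq2, 700 without a filter on low counts, 94 in the fit of all 12 libraries, 84 with a 1.5-fold minimum, which can only remove genes, and 63 to 332 with 1 library left out. The dendritic cell libraries were not paired by number (correlations -0.00175, 0.0122 and 0.0542), and the block gave 214 genes. The 18 interaction genes became 112 by DESeq2, 33 without a filter, 56 with the replicate block and 7 to 19 with 1 library left out. The Fisher p for chromosome 9 ranged over 2.46e-08 to 4.88e-06 in B cells and 4.22e-05 to 0.0412 in dendritic cells. A set test of all its genes by camera, which asks instead for a shift in a common direction, did not pass (0.526 and 0.881). With an estimated correlation 0 sets passed in either cell type, and 0 when combined with the replicate block, against 10 and 10 by camera with the preset correlation. Leaving out 1 library gave 7 to 10 sets in B cells and 9 to 13 in dendritic cells, 10 to 16 shared genes and 12096 to 12573 genes between cell types. The shallowest library, with 8663421 counts, limits what the dendritic cell comparison can show for low genes.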

Other observations

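The comparison of B cell replicate 3 with replicates 1 and 2, and the sums and shares here, were chosen only after the data were seen.

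Replicate 3 of both strains differed from replicates 1 and 2 in B cells far more than the strains did. With strain as a term, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1618 of 15011 genes (10.8%), 486 higher and 1132 lower in replicate 3. The 3 genes with the smallest p-values, named after their values were seen, were Rps27 at a log2 change of -5.58 (SE 0.06), Rpl38 at -4.05 (SE 0.06) and Rpl12 at -2.98 (SE 0.04). No list of ribosomal protein genes was tested. Ribosomal protein genes took 1.33% and 1.47% of counts in replicate 3 of NOD and NOD.Idd2, against 2.37% to 2.55% in replicates 1 and 2. Follicular B cell genes (median log2 0.14, camera adjusted p = 0.0106) were higher and marginal zone genes (-0.20, 0.0106) and cell cycle genes (-0.24, 0.0143) lower as sets in replicate 3, all lost with an estimated correlation (0.750, 0.750 and 0.832). No such shift was tested in dendritic cells.

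H2-Q7 varied within NOD.Idd2. Its level was 2.28, 1.60 and 36.0 CPM in replicates 1, 2 and 3 of NOD.Idd2 B cells and 2.28, 2.31 and 35.4 CPM in replicates 1, 2 and 3 of NOD.Idd2 dendritic cells, on unscaled library totals, against 53.5 to 66.3 and 109 to 133 CPM in NOD. The B cell and dendritic cell libraries of 1 number come from mice of different sex.

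Mitochondrial genes took 1.48 ± 0.0384% of counts in NOD dendritic cells and 1.68 ± 0.0743% in NOD.Idd2 (SD, n = 3), and immunoglobulin genes 0.0814 ± 0.0139% and 0.129 ± 0.0508%.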
